A study of Mus musculus with 3 samples.

How the data were processed

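Poly(A) RNA was measured by high-throughput sequencing in 3 libraries from the hearts of wild-type male mice aged 12 weeks. Per the labels, total RNA was taken with Trizol reagent, poly(A) RNA was captured with probes, and the fragmented RNA was ligated to adaptors. The strain, the read length and the strandedness were not given in the sources used here. The labels place all 3 libraries in a single group and number them 1 to 3, so no contrast between groups was possible. The labels do not say that the libraries came from separate animals, and p-values therefore measure only the spread between these samples, which may be technical.

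The authors deposited whole-number counts per gene symbol for 16587 genes, with no normalization. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM, together with the mouse build GRCm39. The role and order of these tools were not given in the sources used here. RSEM produces estimated counts, so the deposited counts may be estimates rounded to whole numbers, and such estimates divide reads between genes of similar sequence. Near-identical families (Serpina1, Hba and Hbb, Gstp, Eif3j, Entpd4, H2) are therefore uncertain gene by gene, and so are genes that overlap on opposite strands. The table as analysed held 593 genes with 0 counts in every library and 0 mitochondria-encoded genes. Shares of counts refer to the total of this table.

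Gene lengths, GC content and gene classes came from GENCODE M21, an annotation of an earlier mouse build, matched by symbol. They were used as properties of genes and no coordinates were taken from it. A total of 16078 genes (96.9%) matched, and 15876 of these (98.7% of those matched) were annotated as protein-coding. The 509 genes with no match, or with more than 1, stayed in all analyses that needed no length.

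Total counts were 25311388, 26398140 and 24914479 in libraries 1, 2 and 3. A gene with 0 counts could have had up to 3 counts, which is 0.119, 0.114 and 0.120 CPM (counts scaled to a library total of 1000000) in the respective libraries. These floors cover counting error only. A gene was called detected at 1 CPM or more in every library. Levels were given as CPM of the library total, as mean ± SD over the 3 libraries. Length-corrected levels (TPM) were counts per kilobase of annotated exon, scaled to a total of 1000000 over the genes with a length.

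Related genes were compared inside each library as the log2 ratio of counts per kilobase of annotated exon, after 0.5 counts were added. The 40 preset pairs were tested against equal levels with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the 40 pairs and a threshold of 0.05. An exact sign-flip test of 3 libraries cannot give a p below 0.25, so none was used. Genes that differed between the libraries more than other genes of their level were found with edgeR. A negative binomial model with only an intercept was fitted with TMM normalization and the trended dispersion, to genes passing edgeR's default filter of low counts. The deviance was compared with the chi-square distribution and adjusted by Benjamini-Hochberg at 0.05.

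The 55 preset gene lists covered heart muscle, metabolism, stress responses and the cell types and neighbouring tissues that a dissected heart could hold. For each list with at least 5 members past the filter, the members' log2 deviations from their 3-library mean were averaged per library. The SD of these averages was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to vary together when it lay in the top 0.5% of these random lists. Genes are not independent replicates, so this percentile describes these libraries only.

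The 55 gene lists, the 40 pairs, the rule for named genes, and the tests and alternatives of the report were fixed before the data were examined, except the filter described last in this paragraph. The further lists of the closing observations, and the tests on them and on gene copies, were made after patterns had been seen. The text names the 20 genes of highest mean CPM and the genes of the pairs it quotes. From each list it names up to 4 members of highest mean CPM and up to 3 below the detection limit. Of the variable genes with a mean of at least 1 CPM it names the 20 with the largest SD of log2 CPM, and of each list that varied together up to 5 members with the largest SD. Some genes that this rule names are not reported here. The Y-linked genes and Xist were named in advance as a check of the sex; Xist was not in the rows analysed here. Alternatives were other normalizations, filters, length corrections, pseudocounts and detection limits, DESeq2's dispersion trend in place of edgeR's, and leaving out each library in turn. With DESeq2's trend a Pearson statistic also replaced the deviance, so differences cannot be assigned to the trend alone. Calls by DESeq2 refer to that test. A filter keeping genes with at least 30 counts in any 1 library was added after seeing the data, because the default filter removed genes near 0 in any library.

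The procedures were tested on simulated data, with counts drawn at the trended dispersion and independently for each gene. The false calls given here therefore do not cover real genes that scatter around the trend or that move together. For variable genes, simulated over 12521 genes, 55% of those changed 2-fold in 1 library and 96% of those changed 4-fold were recovered, with 4 unchanged genes called, and 0 genes were called where nothing was changed. For pairs, 20 of 20 simulated 2-fold pairs and 1 of 20 equal pairs were called. For lists, 5 of 5 lists shifted 1.5-fold and 0 others were called. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.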

Results

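The transcriptome of the wild-type male mouse heart was measured in 3 libraries at 12 weeks of age. Each library held between 24914479 and 26398140 counts, and 15118, 14883 and 15000 genes had at least 1 count in libraries 1, 2 and 3. A total of 11829 genes reached 1 CPM in every library. The 20 most abundant genes took 18.1%, 17.7% and 17.6% of the counts. Values below are means ± SD over the 3 libraries (n = 3) unless the libraries are given separately. The Y-linked genes Ddx3y (68.4 ± 4.89 CPM), Eif2s3y (39.4 ± 3.95 CPM), Uty (19.3 ± 1.69 CPM) and Kdm5d (14.7 ± 0.66 CPM) were detected in all 3 libraries, whose design text names male mice.

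Log2 CPM of the 12521 genes past the filter correlated between libraries at a Pearson r of 0.986 to 0.988 across genes, which are not independent replicates. The counts of each pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 13.6 to 18.3, so none of them was treated as the same library deposited again, which does not show that they came from separate animals. Between 261 and 340 genes differed more than 2-fold between a pair of libraries.

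The genes with the most counts, which grow with transcript length, included many for the contractile and oxygen-handling proteins of heart muscle. Mb, the muscle oxygen-binding protein myoglobin, stood at 23370 ± 1762 CPM and Myh6, the alpha cardiac myosin heavy chain, at 23308 ± 2627 CPM. They were followed by Tpm1 (14396 ± 622 CPM), the calcium pump Atp2a2 (13157 ± 707 CPM), cardiac actin Actc1 (13067 ± 439 CPM) and the ventricular light chain Myl2 (11373 ± 499 CPM). Tnnt2 (9076 ± 158 CPM), Myl3 (8703 ± 499 CPM), Tnni3 (6817 ± 460 CPM), Mybpc3 (4270 ± 494 CPM) and Tnnc1 (3589 ± 234 CPM) completed the sarcomere genes among the leading 20. The other leading genes were Atp5b (7112 ± 184 CPM), Slc25a4 (6613 ± 227 CPM), Atp5a1 (6407 ± 153 CPM), Pln (6123 ± 266 CPM), Fabp3 (5357 ± 849 CPM), Lpl (4428 ± 96.1 CPM), Ckm (3872 ± 307 CPM), Eef2 (3429 ± 98.3 CPM) and Ogdh (3379 ± 184 CPM). After correction for gene length (TPM) Mb stayed highest of these 20 at 46894, and Actc1 (24224), Fabp3 (19470), Myl2 (17472) and Myl3 (12755) stood above Myh6 (10406), with Tpm1 at 6651. All 24 sarcomere genes were detected and together took 11.5 ± 0.317% of the counts. The 17 calcium-handling genes took 2.65 ± 0.0693%, and 16 were detected. The exception was Sln, an inhibitor of the calcium pump known from atria, with 0, 0 and 1 counts. By edgeR, 0 sarcomere genes varied more than genes of their level when adjusted over all genes tested, 3 did when adjusted over the list alone and 3 at an unadjusted p under 0.05, and DESeq2 called 1, the giant spring protein Ttn (1371, 1111 and 1748 CPM), named after its values were seen.

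**Figure D1:**
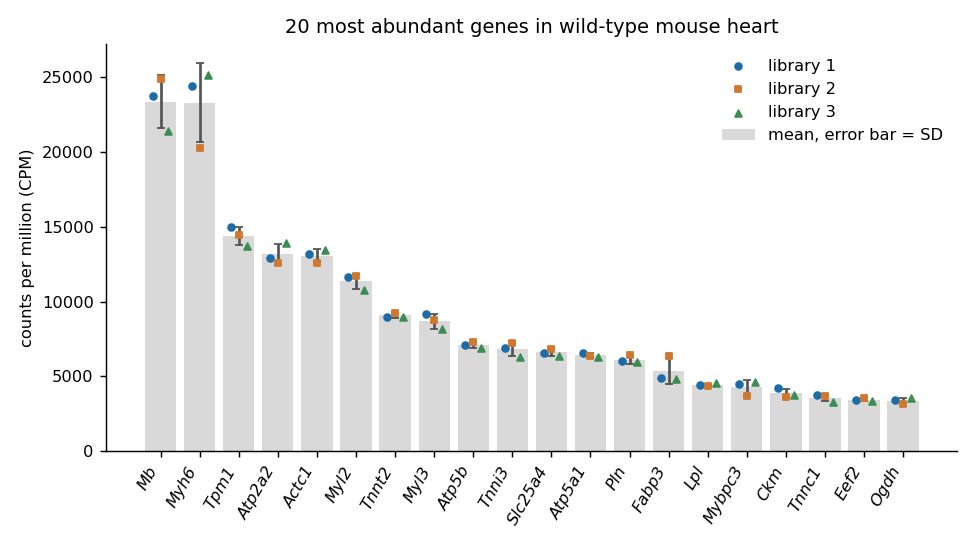
CPM of the 20 most abundant genes, with grey bars for the mean of 3 libraries, error bars for the SD and symbols for each library. Mb and Myh6 stood at 23370 and 23308 CPM, and Ogdh closed the series at 3379 CPM.

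All 10 ventricular genes were detected, against 11 of 14 atrial genes and 5 of 10 genes of the right heart and venous pole. The ventricular list took 3.08 ± 0.125% of the counts and the atrial list 0.184 ± 0.0195%. The number of genes detected does not show how much atrial tissue was present. Among atrial genes Clu (797 ± 68.9 CPM), Pam (604 ± 35.0 CPM) and Nppa (306 ± 133 CPM), the atrial natriuretic peptide, were highest. The atrial light chain Myl7 had 0, 1 and 8 counts, against 11373 CPM for the ventricular light chain Myl2. Sln, known from atria, had 0, 0 and 1 counts. By Myl7 and Sln little atrial muscle RNA was seen in any library, while the atrial genes that were detected leave its amount open. The venous-pole regulators Isl1 and Vsnl1 had 0, 0 and 1 and 1, 0 and 2 counts. Among channels, 20 of 22 genes were detected, among them Abcc9 (368 ± 41 CPM), the connexin Gja1 (215 ± 16.9 CPM) and Kcnip2 (202 ± 20.8 CPM). All 19 cardiac transcription factors and cofactors of the list that were in the table were detected, with Hopx (287 ± 22.5 CPM), Ppargc1a (235 ± 52.9 CPM), Mef2a (194 ± 12.0 CPM) and Mef2d (191 ± 15.4 CPM) highest.

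Genes of energy metabolism were detected without exception among the lists of the respiratory chain (32 nuclear-encoded genes), fatty acid oxidation (24), the tricarboxylic acid cycle (21), glycolysis (19) and energy transfer (11). The respiratory chain took 4.37 ± 0.175% of the counts, led after Atp5b and Atp5a1 by Cox4i1 (2707 ± 208 CPM) and Cox6a2 (2343 ± 165 CPM). When counts were corrected for gene length its share was 6.79%. Fatty acid oxidation took 2.60 ± 0.152%, with Hadha (1909 ± 67.2 CPM) and the fatty acid transporter Cd36 (1589 ± 177 CPM) after Fabp3 and Lpl. The preset tricarboxylic acid cycle list, which holds linked enzymes such as Mdh1, took 2.63 ± 0.0104%, with Mdh1 (2586 ± 84.2 CPM) and Sdha (2049 ± 70.5 CPM) below Ogdh. Glycolysis took 1.53 ± 0.0545%, led by Aldoa (3047 ± 186 CPM), Ldhb (2118 ± 84.3 CPM), Pkm (1611 ± 57.7 CPM) and Eno3 (1506 ± 83.7 CPM). The energy transfer list, which also holds the oxygen-binding protein Mb, took 4.13 ± 0.204%, most of it from Mb and Slc25a4, and 6.91% when corrected for gene length. These shares are therefore not those of energy transfer alone. Oxct1, which activates ketone bodies (1318 ± 20.7 CPM), and Acat1 (716 ± 40.5 CPM) led the 15 genes of ketone and branched-chain amino acid catabolism, all of them detected. Shares of different lists were not tested against each other.

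Within each library, the heart or muscle form exceeded its partner in most of the paired genes. Myh6 exceeded Myh7, the beta myosin heavy chain, by a log2 ratio of 5.75 ± 0.44, or 53.7-fold per kilobase (limma adjusted p = 7.6e-05). Actc1 exceeded skeletal actin Acta1 by 5.65 ± 0.11 on the log2 scale, Ckm exceeded Ckb by 6.34 ± 0.12 and Slc25a4 exceeded Slc25a5 by 4.15 ± 0.05. Among isoforms of cytochrome oxidase, Cox6a2 exceeded Cox6a1 by 4.44 ± 0.05, Cox8b exceeded Cox8a by 3.15 ± 0.17 and Cox7a1 exceeded Cox7a2 by 1.58 ± 0.12. Among fuel genes, Cpt1b exceeded Cpt1a by 4.87 ± 0.14, the insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 by 4.37 ± 0.17, Eno3 exceeded Eno1 by 4.97 ± 0.08 and Ldhb exceeded Ldha by 2.29 ± 0.06. The regulator Mef2a exceeded Mef2c by 1.80 ± 0.07, Ppara was 2.82-fold above Pparg, and Gja1 exceeded Gja5 by 3.23 ± 0.08. Col1a1 was below Col3a1, at -0.66 ± 0.26 (adjusted p = 0.0123). Several partners were near the floor, with Tnni1 at 8, 1 and 1 counts, Actn3 at 13 counts over the 3 libraries, Tnnc2 at 20, Ryr1 at 24 and Atp2a1 at 63, so no fold is given for them.

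All 40 pairs passed 0.05 by limma, 39 with the gene named first higher, and 34 passed a test against a 2-fold difference. Those that did not included Hk2/Hk1 (0.93 ± 0.12), Adra1b/Adra1a (0.94 ± 0.15), Pdk4/Pdk2 (0.73 ± 0.26), Nppa/Nppb (0.51 ± 0.21) and Col1a1/Col3a1, and without library 1 these pairs no longer passed 0.05, at 0.998, 0.94, 0.78, 0.40 and -0.76 in the same order. Nppa/Nppb was also lost without library 3 (0.53). The direction of Adra1b/Adra1a depended on gene length, at -0.43 with no length correction and -0.07 with the longest transcript. Length also set the size of other ratios, and 21 of 40 moved by over 1.5 times with no length correction and 12 with the longest transcript. Under these settings Eno3/Eno1 was 3.34 and 3.72, Cpt1b/Cpt1a 3.69 and 4.26, Ldhb/Ldha 1.21 and 1.69, and Gja1/Gja5 4.07 and 3.98. Cox8b/Cox8a was 2.37 and Cox7a1/Cox7a2 0.76 with no length correction, and Col1a1/Col3a1 was -1.33 with the longest transcript. With the longest transcript Hk2/Hk1 (0.05) and Pdk4/Pdk2 (0.24) also fell short of the threshold.

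**Figure D2:**
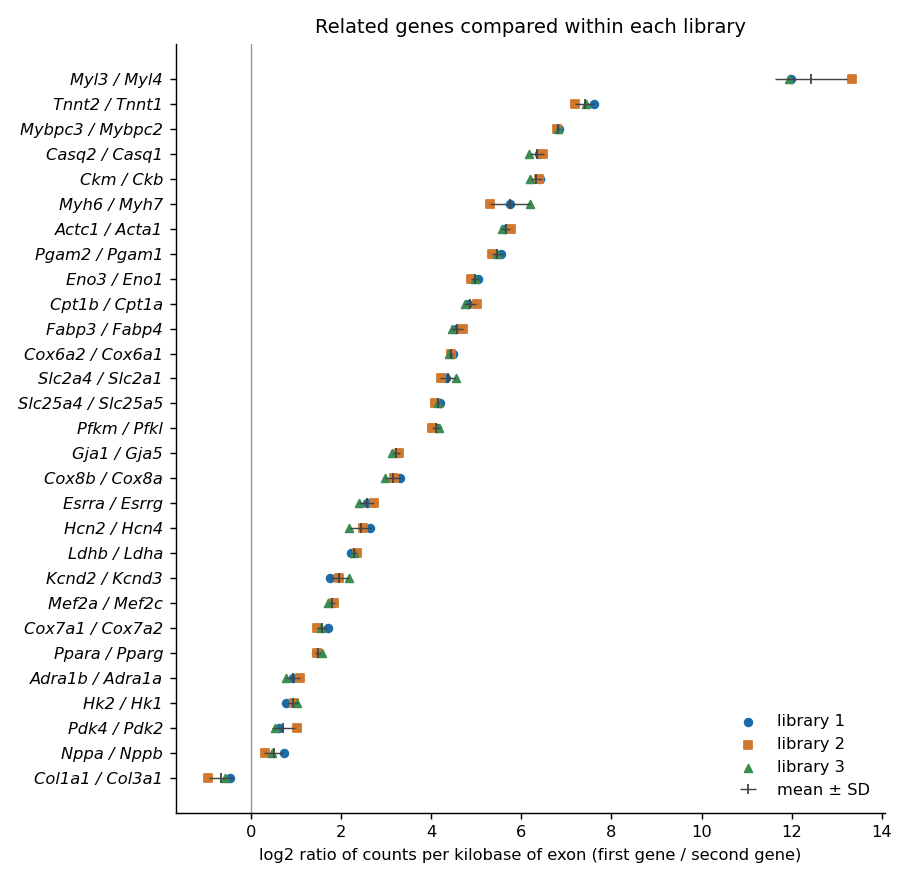
Log2 ratio of counts per kilobase of exon for preset pairs whose second gene had at least 100 counts over the 3 libraries, leaving out pairs with genes not reported here, with a symbol for each library and a bar for mean ± SD. Myh6/Myh7 stood at 5.75 and Col1a1/Col3a1 was the pair below 0, at -0.66; the position of Adra1b/Adra1a above 0 reversed with no length correction and with the longest transcript.

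Markers of the other resident cells of the heart were present at lower shares than the sarcomere genes. All 22 endothelial genes were detected and took 0.730 ± 0.0389% of the counts, led by Cd36, Fabp4 (1221 ± 92.2 CPM), Aqp1 (1063 ± 112 CPM) and Ly6c1 (452 ± 23.3 CPM). All 20 fibroblast genes were detected (0.452 ± 0.0177%), with Gsn (2024 ± 47.4 CPM), Dcn (946 ± 93.0 CPM), Lamc1 (242 ± 38.0 CPM) and Dpt (200 ± 18.1 CPM) highest. Of 20 matrix-remodelling genes 19 were detected, led by Sparc (537 ± 77.9 CPM), and Cthrc1 had 6, 0 and 1 counts. All 12 pericyte genes (0.168 ± 0.0112%) and all 12 smooth muscle genes (0.367 ± 0.0172%) were detected, with Rgs5 (896 ± 88.3 CPM) and Pdgfrb (81.1 ± 2.03 CPM) among the former and Acta2 (250 ± 33.9 CPM) and Smtn (153 ± 11.3 CPM) among the latter. Des and Abcc9, high in these lists, belong also to the sarcomere and channel lists, and Cd36 to fatty acid oxidation. Macrophage genes took 0.142 ± 0.00429% (0.261% when corrected for gene length), with 18 of 19 detected and Lyz2 (459 ± 19.0 CPM), C1qb (153 ± 15.1 CPM) and C1qc (139 ± 12.5 CPM) highest. Cd74 (315 ± 11.7 CPM) led the class II genes, of which 5 of 11 were detected.

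Lymphocyte markers in the table were low. None of 15 T and NK cell genes and none of 9 B cell genes reached 1 CPM in every library. The lists had planned 18 and 14 genes, and the others were not in the table as analysed. Cd3e and Ms4a1 had 0 counts in all 3 libraries, which allows up to 0.114 to 0.120 CPM. Among 14 neutrophil genes 5 were detected, led by Lcn2 (10.4 ± 1.39 CPM) and S100a9 (6.23 ± 2.71 CPM), and Ly6g and Mpo had 0 counts throughout. Proliferation genes took 0.00848 ± 0.000456% of the counts, and 8 of 22 were detected, among them Pcna (44.2 ± 2.11 CPM) and Mki67 (3.62 ± 0.769 CPM).

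Liver genes and some mesothelial genes differed between the libraries. Alb, the serum albumin made by the liver, had 1447, 0 and 29 counts in libraries 1, 2 and 3, so library 1 was at least 503-fold higher than library 2, taken against a floor of 3 counts in that library. Only 4 liver genes passed the filter, too few for the list test, and 3 of them passed the edgeR threshold over all genes and adjusted over the list alone. Of the 13 liver genes 12 were highest in library 1, where the list summed to 236 CPM against 79.8 and 101 CPM in libraries 2 and 3. Trf (77.9 ± 11.1 CPM), the abundant member at similar levels in all 3, made up much of the remainder. Mesothelial genes were highest in library 3 for 11 of 14 members. Msln had 0, 0 and 107 counts, Lrrn4 0, 0 and 42, and Upk3b 2, 0 and 212, and 6 members had counts in library 3 alone. For Msln, library 3 was at least 37.8-fold higher than library 2, against the same floor of 3 counts. The epicardial genes Efemp1 (17.7 ± 1.2 CPM) and Wt1 (15 ± 4.94 CPM) were detected in all 3 libraries. As a whole the mesothelial list lay at the 84.3 percentile and did not pass as varying together, on the 5 of 14 members that passed the filter. The filter removed genes near 0 in any library, such as Msln, Lrrn4 and Upk3b, so this percentile cannot decide whether those vary together.

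**Figure D3:**
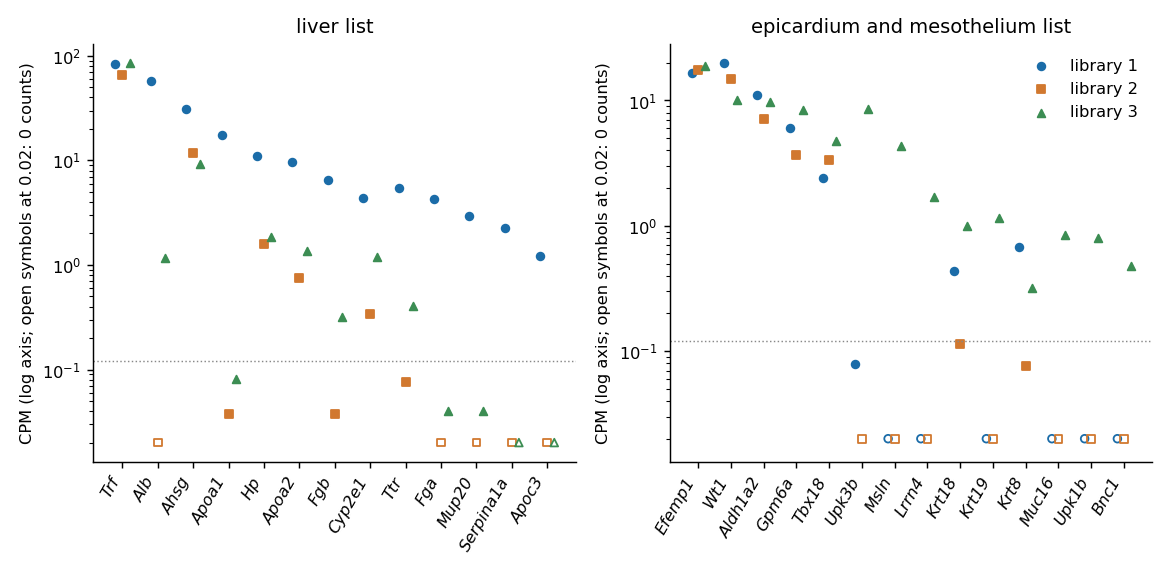
CPM, on a log axis, of each member of the liver list and of the epicardial and mesothelial list in each library; open symbols mark 0 counts and the dotted line the floor of 3 counts. Library 1 was highest for 12 of 13 liver genes and library 3 for 11 of 14 epicardial and mesothelial genes.

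Against genes of the same level, 74 of 12521 genes differed more between the libraries by edgeR after adjustment, and 675 at an unadjusted p under 0.05. The median gene had an SD of log2 CPM of 0.14. Of the 74 genes, 41 were highest in library 1, 14 in library 2 and 19 in library 3. The largest SD of log2 CPM belonged to Entpd4b, with 21, 646 and 26 counts (SD 2.71, edgeR adjusted p = 7.98e-42), a gene with a near-identical copy. Among the 20 genes with the largest SD were proteins secreted by the liver, with Serpina1e at 344, 13 and 38 counts, its close copy Serpina1b at 137, 22 and 18, Apoa2 at 243, 20 and 34, Hp at 280, 42 and 46, and Pzp at 104, 39 and 16. The mast cell proteases Cma1 (27, 12 and 103 counts) and Tpsb2 (26, 35 and 132 counts) were highest in library 3, as were Gstp2 (26, 40 and 138 counts) and the potassium channel Kcnn3 (17, 50 and 105 counts). The chemokines Ccl3 (373, 373 and 85 counts) and Cxcl2 (65, 99 and 13 counts), the immediate early gene Fos (340, 530 and 110 counts) and Aldh1l1 (356, 374 and 91 counts) were lowest in library 3. Gpnmb (844, 207 and 300 counts), Egr3 (113, 21 and 24 counts), Atp6v0d2 (57, 13 and 10 counts), Eif3j2 (322, 46 and 132 counts) and LOC118567800 (76, 11 and 25 counts) were highest in library 1, while Eps8l1 had 19, 276 and 326 counts. Single libraries decided many of these calls. Without library 1 the count was 17 and 14 of these 20 genes were lost, without library 3 it was 39 with 10 lost, and without library 2 it was 51 with 7 lost. DESeq2's dispersion trend called 68 genes and lost 6 of the 20, no filter called 126 and lost 9, and the filter of 30 counts in any library, chosen after seeing the data, called 131 and lost 7. Of the 64 genes that this last filter added, 49 were highest in library 1.

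Of 46 lists tested, 13 varied together, lying in the top 0.5% of random lists. For lists of unrelated genes 0.23 would lie there. Related genes may move together and some lists share members, so no excess over chance was measured. The 13 are given with their mean log2 deviations in libraries 1, 2 and 3. These deviations and the calls of members used only members past the filter, while totals count members in the table. The filter kept 10 of 12 erythroid, 16 of 17 stress and fetal and 14 of 15 glucocorticoid members. It kept 16 of 18 fasting and 7 of 12 mast cell and platelet members, and all members of the other lists. Erythroid genes lay at 0.46, -0.48 and 0.02, with 6 of 12 members past the edgeR threshold both over all genes and adjusted over the list alone. Hba-a2 stood at 157, 60.2 and 102 CPM, Hbb-bt at 177, 71.3 and 108 CPM and Alas2, which starts heme synthesis in red cells, at 67.4, 26.4 and 45.4 CPM. Hba-a1 (342, 155 and 280 CPM) had the same order of libraries, and counts of the near-identical hemoglobin copies are uncertain gene by gene. Immediate early genes, induced within minutes of a stimulus, lay at 0.42, -0.09 and -0.33. Of their 26 members 11 passed over all genes and 19 passed adjusted over the list alone, among them Nr4a1 (112, 43.9 and 40.9 CPM) and Atf3 (23.3, 9.05 and 11 CPM), while Fosb (6.08, 2.84 and 2.73 CPM) did not pass over all genes. Library 1 was highest for 19 of the 26 immediate early genes and library 2 for 7. Fos was highest in library 2 (13.4, 20.1 and 4.42 CPM). Both of these lists kept their call under all 8 alternatives.

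The stress and fetal programme lay at 0.18, -0.04 and -0.13, with 4 of 17 members past the threshold over all genes and 7 adjusted over the list alone. Nppa stood at 460, 225 and 233 CPM (edgeR adjusted p = 7.43e-09), the natriuretic peptide Nppb at 250, 163 and 151 CPM, Lgals3 at 24.0, 10.3 and 10.9 CPM and the metallothionein Mt2 at 116, 86.1 and 68.4 CPM. Genes of endoplasmic reticulum stress lay at 0.14, -0.06 and -0.09, with 0 of 15 members past the edgeR threshold, over all genes or adjusted over the list alone, 2 at an unadjusted p under 0.05 and 0 by DESeq2, and Asns (6.32, 4.36 and 3.53 CPM) and Chac1 (17.4, 10 and 13.6 CPM) most spread. Glucocorticoid-responsive genes lay at 0.08, 0.04 and -0.12, with Errfi1 (121, 78.2 and 57.0 CPM) and Mt2 past the threshold, 2 of 15 both over all genes and adjusted over the list alone. Without library 1 the stress and fetal list was at the 86.2 percentile and the endoplasmic reticulum list at 33.2. The glucocorticoid list was at 12.7 without library 3, and at 99.3 after correction for gene length, GC content and level, where it no longer passed.

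The fasting, respiratory chain and ribosomal protein lists were highest in library 2. Fasting and PPAR-alpha targets lay at -0.06, 0.19 and -0.13, with the uncoupling protein Ucp3 at 52.8, 90.8 and 47.2 CPM as the 1 of 18 members past the threshold over all genes and 3 adjusted over the list alone; Angptl4 stood at 12.6, 19.3 and 10.8 CPM and Plin5 at 137, 213 and 149 CPM. Ribosomal protein genes lay at -0.03, 0.14 and -0.11, and 34 of 35 were highest in library 2, though only Rps27a (120, 201 and 119 CPM) passed by itself, over all genes and over the list alone. The nuclear-encoded respiratory chain lay at 0.01, 0.08 and -0.09, with 28 of 32 genes highest in library 2 and 0 past the threshold by edgeR over all genes, adjusted over the list alone or unadjusted, and 0 by DESeq2; Cox8b (684, 698 and 558 CPM) and Cox7b (990, 1183 and 987 CPM) were most spread. Without library 2 the fasting list was at the 80.3 percentile and the ribosomal list at 98.5. The respiratory chain was at 97.2 without library 3 and at 87.9 after correction for length, GC content and level, where it no longer passed.

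The fibroblast, smooth muscle, lymphatic, mast cell and platelet, and interferon lists were highest in library 3. Other vascular lists did not pass, with endothelial genes at the 96.8 percentile, endocardial genes at 99.2 and highest in library 1, and pericyte genes at 6.11. The endothelial list passed at 99.7 after correction for gene length, GC content and level, and the endocardial list passed at 99.7 without library 3. The fibroblast list lay at -0.10, -0.05 and 0.15, with 3 of 20 members past the threshold over all genes and 5 adjusted over the list alone. Among them Col3a1 stood at 92.5, 138 and 177 CPM and Col1a1 at 45.1, 47.7 and 79.8 CPM, while Pi16 had the opposite order at 155, 113 and 73.2 CPM. The smooth muscle list lay at -0.11, -0.12 and 0.23, with Cnn1 at 7.55, 7.08 and 13.1 CPM and Myh11 at 109, 97.6 and 153 CPM; by edgeR 0 of 12 passed over all genes, 1 adjusted over the list alone and 4 at an unadjusted p under 0.05, and by DESeq2 0 passed. Mast cell and platelet genes lay at -0.08, -0.54 and 0.62 (2 of 12 past the threshold over all genes and 5 adjusted over the list alone), with the mast cell protease Mcpt4 at 1.86, 1.14 and 4.13 CPM. The platelet gene Itga2b was highest in library 1 instead (2.45, 1.21 and 1.28 CPM). Lymphatic endothelial genes lay at 0.08, -0.32 and 0.23, with Reln (11.7, 5.72 and 17.5 CPM) and Mmrn1 (18.5, 12.5 and 29.4 CPM) past the threshold, 2 of 8 both over all genes and adjusted over the list alone. Interferon-stimulated genes lay at 0.03, -0.15 and 0.12, with Usp18 (5.06, 2.99 and 5.58 CPM) and Ifit2 (15.4, 9.70 and 16.9 CPM) most spread and 0 of 21 past the edgeR threshold over all genes or adjusted over the list alone, 5 at an unadjusted p under 0.05 and 0 by DESeq2. Without library 3 the fibroblast list was at the 71.3 percentile, smooth muscle at 9.81, mast cell and platelet at 94.3 and interferon-stimulated genes at 99.2. Without library 2 the lymphatic list was at 81.9 and the interferon list at 79.9.

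**Figure D4:**
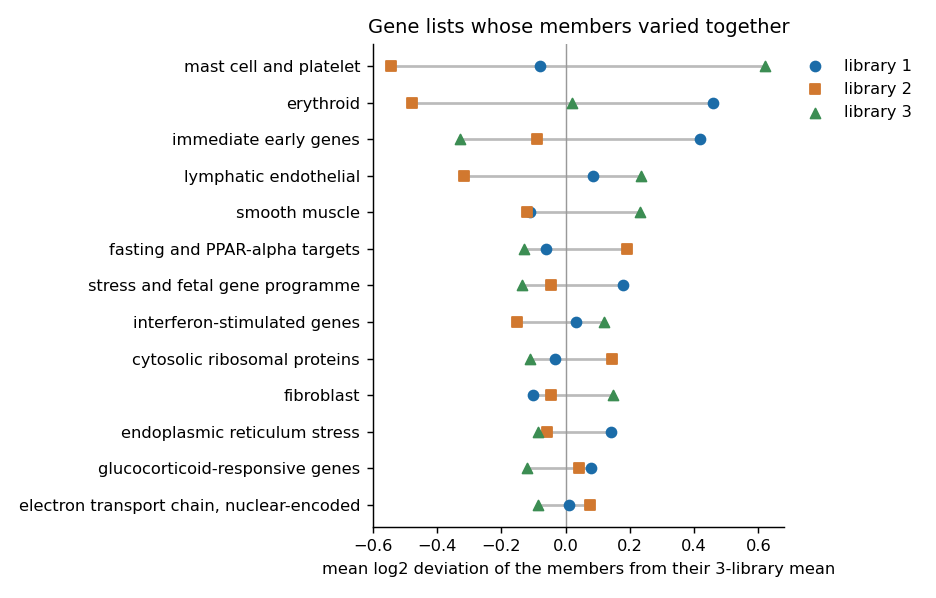
Mean log2 deviation of the members of each of the 13 lists that varied together, with a symbol for each library and a grey line for their range. Erythroid and immediate early genes were highest in library 1 at 0.46 and 0.42, and mast cell and platelet genes in library 3 at 0.62; the respiratory chain and glucocorticoid lists no longer passed after correction for gene length, GC content and level.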

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

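The filter of 30 counts in any library was chosen after the results were seen; all other alternatives were planned. For the agreement between libraries, the lowest Pearson r of 0.986 became 0.961 with no filter and 0.991 as a Spearman correlation. The length-corrected share was 6.79% for the respiratory chain and 3.58% for fatty acid oxidation, while sarcomere and glycolysis shares moved by less than 1 SD. Against 74 variable genes by edgeR, no filter gave 126 (65 shared with the 74) and the filter of 30 counts gave 131 (67 shared). Leaving out each library gave 17 to 51, with fewer samples in each test; the cause of the other changes was not tested. Size factors of DESeq2's kind gave 74, all shared, at least 1 CPM in every library gave 64 and DESeq2's trend 68. The log2 ratio of Adra1b/Adra1a reversed to -0.43 with no length correction and to -0.066 with the longest transcript, by construction, since only the lengths were altered. Between 34 and 40 pairs passed in every alternative run, and between 10 and 16 lists, against 13. Detected list members numbered 617, and 668 or 679 with looser limits. The alternative that leaves mitochondria-encoded genes out of the total was not run, because the table as analysed held 0 of them. No paired analysis was possible because the labels give a single group. Depth limited genes under about 0.12 CPM, and 55% of simulated 2-fold changes in 1 library were recovered.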

Other observations

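The tests of enzymes near 0 in library 2, of acute-phase genes and of the 3 gene copies were chosen only after the results were seen; the tests of all hepatocyte enzymes, of vessel wall and valve genes and of the length and GC trend were written before theirs.

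Receptor and hormone genes of the heart were mostly detected. Of the 17 adrenergic and muscarinic genes 15 reached 1 CPM in every library, led by the G protein subunits Gnas (1150 ± 34.5 CPM, SD, n = 3) and Gnai2 (493 ± 18.2 CPM), while Adrb3 had 0, 6 and 7 counts. Of 17 renin-angiotensin and natriuretic genes 15 were detected, among them Corin, the protease that cleaves the natriuretic peptide precursor (229 ± 18.6 CPM), and Ace (151 ± 19.0 CPM), and Agtr2 had 0 counts in all 3 libraries. All 18 clock genes were detected, led by Tef (208 ± 13.4 CPM) and Nr1d2 (128 ± 3.06 CPM). All 18 chaperone genes were detected, with the small heat shock protein Hspb7 (3208 ± 98.1 CPM) and Hspa8 (2153 ± 40.4 CPM) highest. Of 16 hypoxia-responsive genes 15 were detected, and Car9 had 1, 0 and 2 counts. The 10 antigen presentation genes, led by B2m (550 ± 52.7 CPM), did not vary together, at the 1.51 percentile, with 2, 4 and 4 members highest in libraries 1, 2 and 3.

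Marker genes of fat cells, nerves and neighbouring organs were detected in part. Of the white adipocyte genes 8 of 15 were detected, at 0.242 ± 0.0103% of the counts and led by Fabp4 and Pnpla2 (568 ± 40.5 CPM), and of the brown adipocyte genes 7 of 13, at 0.243 ± 0.0102% (0.171% and 0.993% when corrected for gene length), the latter led by Cpt1b and Cox8b, which are also in the heart metabolism lists. The adipocyte hormones Lep (0, 0 and 1 counts) and Retn (4, 1 and 5 counts) and the fat cell gene Cidec (1, 1 and 10 counts) were near the floor, and Ucp1, the uncoupling protein of brown fat, had 0 counts in every library. Stmn2 (15.4 ± 0.665 CPM) and Dbh, which makes noradrenaline (4.19 ± 1.30 CPM), were among the 5 of 11 nerve genes detected, and 11 of 13 Schwann cell genes were detected, led by Pmp22 (111 ± 8.17 CPM). Of 16 skeletal muscle genes 5 were detected, including Eno3 and Acta1, which heart muscle also expresses, while Myh1 and Myf6 had 0 counts. The lung list was represented by Hopx, a gene of the cardiac list, and the thymus list had 0 of 6 genes detected. Only 6 of 12 planned lung genes and 6 of 10 planned thymus genes were in the table as analysed. Tg (1.90 ± 0.257 CPM) was the 1 thyroid gene detected.

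Liver transcripts were highest in library 1 for 12 of 13 genes, and liver RNA in that library is a candidate explanation. A list of 20 hepatocyte enzymes outside the liver list was highest there for 18, but their sum was 2.28 times the mean of libraries 2 and 3, short of the 5-fold set in advance and above the bound of 1.5 against it; members above 1 CPM in all 3 libraries, such as Ass1 (182, 220 and 158 counts), made up most of it. The 13 enzymes with at most 3 counts in library 2 were 18 times as high in library 1 as in library 3, at 329 against 18 counts, and beside them stood Alb at 1447, 0 and 29 counts. An acute-phase response of the heart was tested with 8 such genes made outside the liver, which summed to 0.909 times the other libraries. C3 (0.909) and Cp (0.802) set that sum. The members went both ways, with S100a8 and S100a9 at 2.16 and 1.65 and the other 6 between 0.099 and 1.2 times the other libraries. Such a response was argued against as the whole cause, since 18 of 20 hepatocyte enzymes outside that list were highest in library 1. Alb was at least 503-fold higher there than in library 2, against at most 2.16 times for the 8 genes. A part of it in acute-phase genes stayed open. Whether any liver RNA came from tissue, carry-over or shared sequencing was not tested, and the design, with a single group, gives no biological contrast to set against it.

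The smooth muscle and fibroblast lists were on average highest in library 3, for 10 of 12 and 13 of 20 members. So were 11 of 14 epicardial and mesothelial genes. That list did not pass as varying together (84.3 percentile), but only 5 of its 14 members passed the filter. Genes near 0 in any library, such as Msln (0, 0 and 107 counts), were removed, so this percentile cannot decide the pattern. A trend with gene length, GC content or level was argued against as the whole cause for smooth muscle, which stayed at the 99.9 percentile after correction for all 3. A larger piece of vessel wall or valve could not be told apart from other sources, because the 11 genes past the filter, of a list of 16 matrix genes of those tissues, lay at the 98.9 percentile, between the bounds set in advance, the 95 percentile against it and the top 0.5% for it; it was highest in library 3 on average, and 10 of 16 genes were. Different amounts of outer heart tissue in the dissected pieces may also be involved but were not tested, and no biological explanation was tested.

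Entpd4b, Eif3j2 and Gstp2, each with a near-identical copy, differed between libraries. For Entpd4b a different division of reads with Entpd4 was argued against, since Entpd4 had 1, 2 and 2 counts and gained -0.00153 of the change. For Eif3j2 and Gstp2 it could not be told apart from a change in level. The partners Eif3j1 (1322, 1668 and 1497 counts) and Gstp1 (2570, 2729 and 2172 counts) gained 0.998 and 3.18 times the change. The changes of 11 and 4.51 CPM were under 2 times the spread between libraries expected for the partners from genes of their level (6.02 and 9.05 CPM). Other copies of these genes, and genetic differences between animals or against the reference, may contribute and were not tested.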
